A study of Mus musculus with 19 samples.

How the data were processed

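The series holds bulk RNA sequencing of cerebellum from 19 separate mice, so the p-values measure spread between animals. By the labels, RNA was taken up in Trizol, purified with RNeasy columns, made into TruSeq libraries from 1 ug of total RNA and sequenced on an Illumina HiSeq. The submitters' notes name TopHat, Cufflinks and the mm9 assembly. Their versions, the annotation, the read totals and the sex of the mice were not given in the sources used here. The reads were not used here, so alignment, strandedness, duplication and splicing could not be examined.

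The deposited tables hold FPKM of 22193 genes for each library, 1 table for each knockout with the Ctrl libraries in both, and 2605 genes are at 0 in all 19 libraries. Ctrl 2 and 3 are identical between the tables. Ctrl 1 differs in 5106 genes with a median ratio of 1.0 and a 5th to 95th percentile of 0.999 to 1.001, so the scale is common and the knockouts were compared directly; each comparison with Ctrl used the Ctrl values of its own table, and list scores, correlations between libraries and chromosome shifts used those of the table of Olig1-Gnas. Symbols of 25 genes had been turned into dates and were kept as listed. An exact 0 can be a failed estimate: 461 genes, 165 to 286 in a library, were at 0 in some libraries while every library above 0 had at least 1 FPKM, as did 39 of the 8485 genes called for Olig1-Gnas, 19 of the 5570 called for hGFAP-Gnas and 0 of the 59 called between knockouts. Relative depth was inferred from genes under 0.5 FPKM in a library and in Ctrl 2, whose values rest on a few fragments. The commonest ratio of these values gave the depth, libraries under 0.6 formed the shallower class, and 39.9 to 49.7% of low values lay at ratios of small whole numbers, against 3.43 to 7.36% at shifted ratios. FPKM summed to 508329 to 525832 per library in Ctrl, 603067 to 689165 in Olig1-Gnas and 505739 to 659634 in hGFAP-Gnas, lowest in hGFAP-Gnas 1. The main test did not remove this difference between groups. Ddx3y stood at 13.1 to 25.1 FPKM where Y-linked signal was present and at most 0.0980 FPKM elsewhere.

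Genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 1) with limma, using trend and robust moderation, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The offset of 1 makes folds of low genes smaller than their ratios. FPKM is already divided by a library total, so no further scaling was applied in the main test. The Ctrl libraries are shared, so both knockout comparisons depend on the same 3 animals. Gnas was also tested by permuting library labels, with 165 arrangements and a smallest possible p of 0.00606. Planted changes of 1.5, 2 and 4 times in 200 genes, over 20 runs, were recovered in 15.9, 51.8 and 88.0% for Olig1-Gnas, 8.73, 39.6 and 81.4% for hGFAP-Gnas and 28.5, 63.7 and 92.0% between knockouts, with a mean of 6.7, 4.1 and 10.05 false calls. A planted list was called in 20 of 20 runs and an unchanged list in 0. Noise was drawn for each gene on its own, so these runs do not test lists of genes that move together.

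Gene lists, 29 in number with 352 genes, were written from general knowledge before the data were examined, and 28 had enough tested members. They cover hedgehog targets and pathway components, granule progenitors, mature granule neurons, Purkinje cells, inhibitory interneurons, Bergmann glia and astrocytes, mature oligodendrocytes, oligodendrocyte precursors, microglia and macrophages, vascular cells, choroid plexus, meninges, blood, T lymphocytes, DNA replication, mitosis, cell cycle inhibitors and p53 targets, cAMP signaling, immediate early genes, Hippo signaling, neural stem cells, markers of 4 medulloblastoma subgroups, chromatin regulators, interferon response and synapses. Lists were tested with camera at its preset correlation of 0.01 and at an estimated correlation, and with fry. Counts of called members were also taken with p-values adjusted over the list alone. Ppp1r17, Trac, Hbb-bs and Hbb-bt are not in the tables, and Disp1 and Mbp are at 0 everywhere.

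The main test, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named Gnas, up to 4 called members of each list with the largest folds, hedgehog targets and granule progenitor genes, the 10 largest changes in each direction, and for the knockout pair 5 genes in each direction. Depth classes, the Y-linked term and zeros as missing were added after seeing the values. Alternatives changed the offset (0.1), the filter (none, or 5 FPKM in a group), the scaling, the moderation, the threshold (0.01, or 2-fold), the design and the libraries, leaving out each in turn. Groups were also shuffled 100 times, and each knockout group of named genes and lists was searched for a single distant library with Dixon's ratio at the 0.05 level. Locations are those printed in the tables. Results of some genes that the naming rule covers are not reported here. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.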

Results

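RNA from the cerebellum of 19 mice of the strain C57BL/6 was sequenced at postnatal day 60. The groups were 3 wild-type mice (Ctrl), 8 mice with Gnas deleted by Olig1-Cre (Olig1-Gnas), and 8 with Gnas deleted by hGFAP-Cre (hGFAP-Gnas). Gnas encodes Gsα, the G protein subunit that stimulates adenylyl cyclase. The series' title names Gsα as a tumor suppressor in medulloblastoma driven by Sonic hedgehog, so the comparisons ask how each knockout cerebellum differs from wild type and how the knockouts differ from each other. The deposited values were FPKM of 22193 genes. Those of hGFAP-Gnas carry the word tumor in their name, and those of Olig1-Gnas do not. A difference from Ctrl may thus be one of tumor against normal tissue rather than of Gnas loss in otherwise normal cerebellum. Read totals were not given in the sources used here, so the depth in reads is unknown; steps among the lowest values gave the depth relative to Ctrl 2. Ctrl 1 and 2, Olig1-Gnas 5 to 8 and hGFAP-Gnas 1 to 4 were the deeper libraries, at 0.838 to 1.07 of Ctrl 2. Ctrl 3, Olig1-Gnas 1 to 4 and hGFAP-Gnas 5 to 8 were the shallower ones, at 0.268 to 0.429. The labels used here give no sex, and the Y-linked gene Ddx3y reached 1 FPKM in 2 of 3 Ctrl, 2 of 8 Olig1-Gnas and 7 of 8 hGFAP-Gnas libraries. Levels below are mean ± SD over n = 3 Ctrl or n = 8 knockout libraries, folds are on the scale of log2(FPKM + 1) with their SE, and adjusted p-values are limma's unless another test is named.

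The targeted gene Gnas could be read only in part, because a listed 0 need not mean absence: Rps27a, of the small ribosomal subunit, and Mbp, of myelin, are listed at 0 in all 19 libraries. In the table of Olig1-Gnas, Gnas stood at 651 FPKM in Ctrl 1, 798 FPKM in Ctrl 2 and at 0 in Ctrl 3. Olig1-Gnas 2, 3, 4, 5 and 7 held 117, 24.0, 33.3, 52.9 and 121 FPKM, and Olig1-Gnas 1, 6 and 8 are listed at 0. In the table of hGFAP-Gnas, Ctrl 2 held 798 FPKM, Ctrl 1 and 3 are listed at 0, hGFAP-Gnas 5 held 40.9 FPKM, and the other 7 knockout libraries are listed at 0. Every knockout value above 0 lay below every Ctrl value above 0. With zeros as listed, Gnas did not differ in Olig1-Gnas (log2 difference -2.67, two-sided exact permutation p = 0.388) or in hGFAP-Gnas (-2.54, two-sided exact permutation p = 0.273). Single Ctrl libraries moved these differences. In Olig1-Gnas the difference was -1.01 without Ctrl 2 and -5.83 without Ctrl 3. In hGFAP-Gnas it turned to 0.67 without Ctrl 2 and was -4.15 without Ctrl 1. With zeros taken as missing, a choice made after seeing the data, the difference in Olig1-Gnas was -3.63, with an exact permutation p of 0.0476, the smallest that 21 arrangements can give. For Olig1-Gnas, limma gave an adjusted p of 0.372 with zeros as listed. With zeros as missing its fold was -3.63 ± 0.62 (adjusted p = 0.00120), with Ctrl 1 and 2 as the only Ctrl libraries. Loss of the targeted transcript in each knockout library was therefore not shown by these values.

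In the Olig1-Gnas cerebellum, genes of cell division, of the Sonic hedgehog response and of granule neuron progenitors rose, and genes of mature granule neurons, Purkinje cells, inhibitory interneurons and myelinating oligodendrocytes fell. The rises were large: all 17 mitosis genes and all 16 DNA replication genes rose. Top2a, the topoisomerase that untangles replicated DNA, went from 0.308 ± 0.0412 to 163 ± 49.6 FPKM (log2 fold 6.92 ± 0.23). Mki67, which encodes the proliferation marker Ki-67, went from 0.243 ± 0.0727 to 156 ± 62.5 FPKM (log2 fold 6.89 ± 0.31). Birc5, an inhibitor of apoptosis active in mitosis, rose by 6.30 ± 0.15 on the log2 scale, and Mcm6, part of the replicative helicase, by 6.30 ± 0.20. The camera test with its preset correlation called both lists higher (adjusted p = 1.64e-13 and 1.87e-10), and neither passed with an estimated correlation (adjusted p = 0.163 for each). Of 14 cell cycle inhibitors and p53 targets, 11 rose and 1 fell. Cdkn2a, which encodes p16 and ARF, reached 60.3 ± 58.2 FPKM from 0.195 ± 0.116 FPKM. Eda2r, a p53 target, rose by 4.34 ± 0.24 and Cdkn2c, which encodes p18, by 4.12 ± 0.21 on the log2 scale (camera adjusted p = 0.00529, and 0.145 with an estimated correlation).

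Of 12 measured hedgehog targets, 11 rose and none fell. Gli1, the transcription factor whose level reads out the pathway, went from 7.66 ± 0.740 to 87.3 ± 18.7 FPKM (log2 fold 3.33 ± 0.18, adjusted p = 3.12e-08); it lies on chromosome 10 at 126760782 to 126778635 of mm9. The receptor gene Ptch1, itself a target, went from 48.9 ± 2.47 to 168 ± 78.5 FPKM (log2 fold 1.65 ± 0.32). Mycn and Ccnd1, which drive progenitor division, rose by 5.20 ± 0.26 and 4.42 ± 0.21 on the log2 scale, and the secreted WNT modulator Sfrp1 by 5.36 ± 0.39. Nkx2-2 stood at 4.21 ± 0.338 FPKM in Ctrl and 2.71 ± 1.93 FPKM in Olig1-Gnas (adjusted p = 0.193). Of 13 hedgehog pathway components, 6 rose and 2 fell: Smo, the signal transducer, rose by 2.57 ± 0.18, Sufu, a repressor of GLI proteins, by 1.88 ± 0.25, and the coreceptor gene Cdon fell (log2 fold -2.48 ± 0.34). Of 14 granule progenitor genes, 11 rose. Atoh1, the transcription factor that defines these progenitors, went from 0.104 ± 0.0815 to 92.2 ± 59.2 FPKM (log2 fold 6.13 ± 0.52), Barhl1 rose by 4.69 ± 0.18, Nhlh1 by 6.82 ± 0.30 and Igfbpl1 by 6.68 ± 0.31. Cntn2, Tlx3 and Zic5 had log2 folds of -0.05, 0.29 and -0.05 that did not pass the test. Targets and progenitor genes were called higher as lists (camera adjusted p = 4.92e-05 and 1.41e-05, and 0.145 for each with an estimated correlation), and the components were not called as a list (0.470).

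Genes of mature neurons fell. Of 14 genes of mature granule neurons 13 fell. Gabra6, a GABA receptor subunit of these cells, went from 354 ± 123 to 17.9 ± 31.1 FPKM (log2 fold -6.09 ± 1.37) and Slc17a7, a vesicular glutamate transporter, had a log2 fold of -5.50 ± 1.08. All 13 Purkinje genes fell. The calcium buffer gene Calb1 went from 344 ± 113 to 16.8 ± 28.8 FPKM (log2 fold -6.03 ± 1.33), and Car8 had a log2 fold of -5.41 ± 1.09. Of 11 genes of inhibitory interneurons 8 fell, among them the GABA synthesis gene Gad1 at -5.11 ± 1.16 and the vesicular GABA transporter Slc32a1 at -4.65 ± 0.90. These lists were called lower (camera adjusted p = 1.24e-05, 1.49e-06 and 1.05e-04), and with an estimated correlation their adjusted p was 0.295, 0.284 and 0.287. Gabra6 stood at 75.7 and 59.8 FPKM in Olig1-Gnas 7 and 8, and at most 3.27 FPKM in the other 6. Of 20 genes of cAMP signaling, a list that includes Gnas itself, 12 fell and 4 rose. The adenylyl cyclase gene Adcy1 fell by a log2 fold of -4.49 ± 0.74, Gnal, which encodes the olfactory relative of Gsα, had -3.18 ± 0.65, and the protein kinase A subunit gene Prkar1b -2.67 ± 0.47 (camera adjusted p = 0.00150, and 0.242 with an estimated correlation). Of 14 immediate early genes that cAMP or activity induce, 7 fell, 6 when adjusted over the list alone, including Arc (-2.07 ± 0.29) and Bdnf (-1.64 ± 0.21; camera adjusted p = 0.00150, and 0.305 with an estimated correlation).

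Glial and immune genes moved in several directions. All 13 measured genes of mature oligodendrocytes fell. Mog, at the myelin surface, went from 35.4 ± 5.11 to 2.79 ± 2.30 FPKM (log2 fold -3.48 ± 0.48; list camera adjusted p = 1.63e-06, and 0.287 with an estimated correlation). Of 11 oligodendrocyte precursor genes, 4 rose and 1 fell. Pdgfra, the growth factor receptor of precursors, went from 5.59 ± 0.535 to 68.7 ± 17.4 FPKM, Olig2 rose by 2.33 ± 0.27 on the log2 scale, and the list was not called (camera adjusted p = 0.217). Of 15 genes of microglia and macrophages 11 rose and none fell. Cd68, a lysosomal protein of phagocytes, went from 3.63 ± 0.467 to 67.7 ± 27.2 FPKM (log2 fold 3.81 ± 0.29) and the complement gene C1qb rose by 3.79 ± 0.41 (list camera adjusted p = 0.00150, and 0.475 with an estimated correlation). Genes of Bergmann glia and astrocytes were split: 7 of 14 fell, 8 when adjusted over the list alone, and 3 rose. Gdf10, a Bergmann glia factor, went from 109.9 ± 38.2 to 14.2 ± 9.72 FPKM (log2 fold -3.21 ± 0.72), and Aldoc had a log2 fold of -3.76 ± 1.12 (list lower, camera adjusted p = 0.0279, and 0.591 with an estimated correlation). Of 17 lists that camera called here, the Bergmann glia list alone did not pass fry (adjusted p = 0.0773). Of 12 vascular genes 2 fell, Flt1 (-1.02 ± 0.29) and Pdgfrb (-0.77 ± 0.26), and none did when adjusted over the list alone. Markers of choroid plexus varied with the library in every group: Ttr, the main transcript of its epithelium, stood at 1195 FPKM in Ctrl 3 and 2317 FPKM in Olig1-Gnas 8. For the other lists named here, the counts adjusted over the list alone equaled those over all genes.

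In total 8485 of 14183 tested genes were called at an adjusted p under 0.05, 5134 higher and 3351 lower, and 4955 of them changed at least 2-fold. The share of higher genes was 60.5%, and it was 51.4% after quantile normalization and 51.2% after upper quartile scaling. The median fold of all tested genes was 0.22 on the log2 scale; quantile normalization moved it to 0.06 and upper quartile scaling to 0.04, and no named gene or list called here turned direction under either. Within depth classes, 6211 genes were called among the deeper libraries, where Gabra6, Cbln3, Flt1 and Pdgfrb lost their calls, and 5141 among the shallower ones, where 1 Ctrl library remains and is assumed to vary like the others and Aldoc, Gdf10 and Pdgfrb lost theirs. In total 8587 were called with the class and 7739 with Y-linked signal as a term. Leaving out Ctrl 2 ended the calls of Aldoc and Pdgfrb, and leaving out Ctrl 3 those of Flt1 and Pdgfrb.

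**Figure D1:**
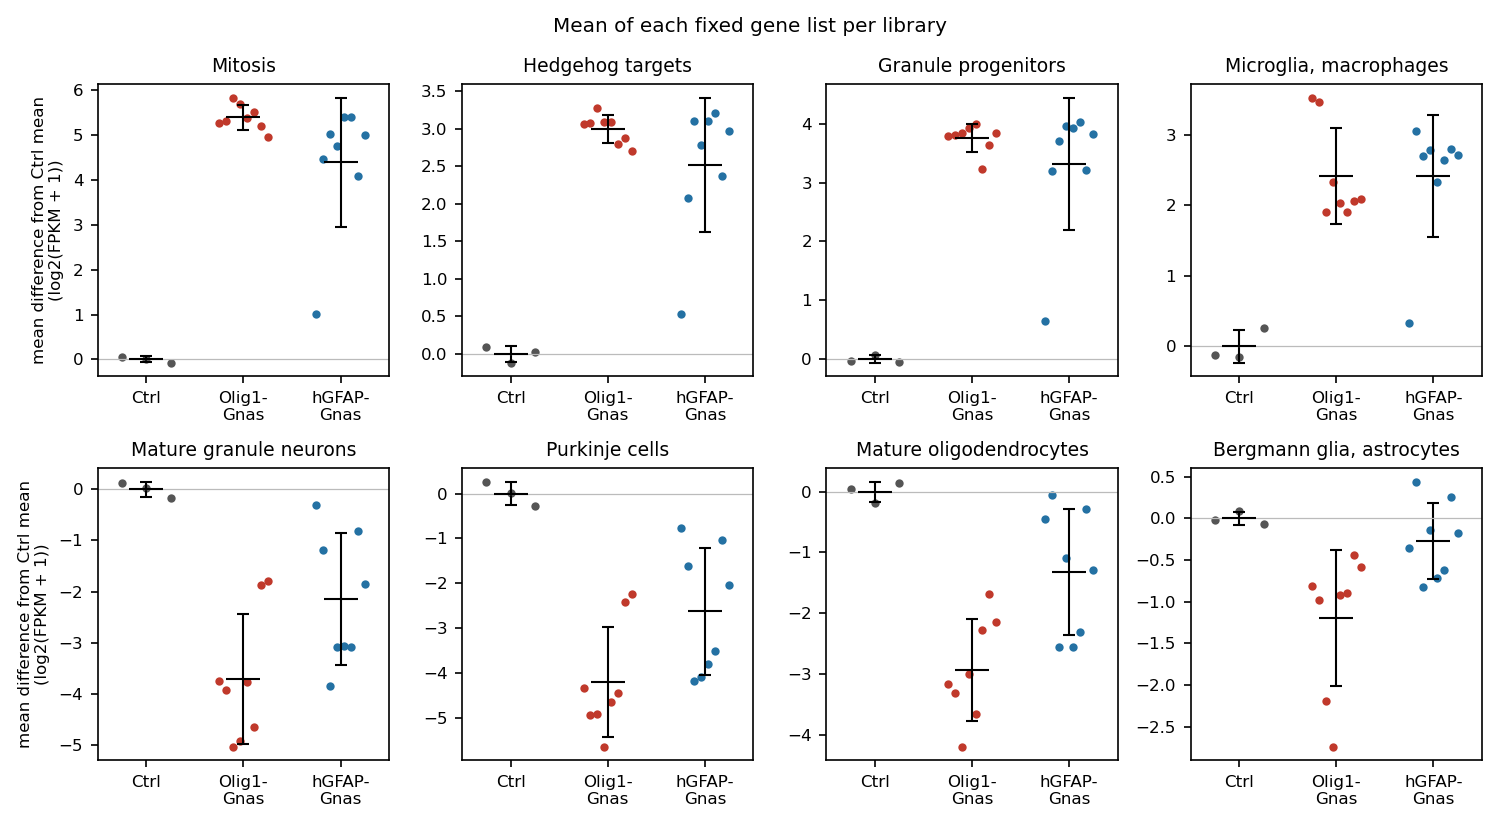
Mean of 8 fixed gene lists in each library, as the difference from the Ctrl mean of log2(FPKM + 1); each point is a library, the horizontal line the group mean and the bar the SD (n = 3, 8 and 8). Mitosis genes averaged 5.40 ± 0.28 in Olig1-Gnas and 4.39 ± 1.44 in hGFAP-Gnas, where hGFAP-Gnas 1 stood at 1.00, and Purkinje genes averaged -4.19 ± 1.22 and -2.62 ± 1.41.

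In the hGFAP-Gnas cerebellum too, genes of cell division, of the hedgehog response and of granule progenitors rose, and genes of mature granule neurons, Purkinje cells and inhibitory interneurons fell. All 17 mitosis and all 16 replication genes rose. Top2a went from 0.308 ± 0.0412 to 99.6 ± 58.0 FPKM (log2 fold 5.74 ± 0.96), Mki67 from 0.243 ± 0.0727 to 92.9 ± 57.6 FPKM (5.69 ± 0.95) and Mcm6 from 0.855 ± 0.479 to 101 ± 51.0 FPKM (5.39 ± 0.84). Of 12 hedgehog targets 9 rose, 10 when adjusted over the list alone, and none fell. Gli1 went from 7.66 ± 0.740 to 53.9 ± 20.9 FPKM (log2 fold 2.55 ± 0.36, adjusted p = 0.00520), Mycn rose by 4.48 ± 0.87, Ccnd1 by 3.37 ± 0.84 and Sfrp1 by 5.09 ± 0.94 on the log2 scale. Ptch1 stood at 106 ± 39.5 FPKM, against 48.9 ± 2.47 FPKM in Ctrl, and missed the threshold (log2 fold 0.98 ± 0.37, adjusted p = 0.0555). Of 13 pathway components 4 rose, among them Smo (1.76 ± 0.40) and Sufu (1.71 ± 0.35), and 2 fell, Cdon (-1.73 ± 0.62) being one. Of 14 granule progenitor genes 11 rose: Atoh1 went from 0.104 ± 0.0815 to 59.4 ± 43.2 FPKM (log2 fold 5.16 ± 1.01), Nhlh1 rose by 5.90 ± 0.89 and Igfbpl1 by 6.29 ± 0.90. Of 14 cell cycle inhibitors and p53 targets 8 rose, 9 when adjusted over the list alone, and 1 fell, with Cdkn2a going from 0.195 ± 0.116 to 6.98 ± 5.28 FPKM (log2 fold 2.43 ± 0.60). Mitosis, replication, hedgehog target, progenitor and inhibitor lists were called higher (camera adjusted p = 7.69e-08, 2.65e-06, 1.35e-04, 1.28e-04 and 0.0143); with an estimated correlation each had an adjusted p of 0.392. The component list was not called (camera adjusted p = 0.545).

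Neuronal genes fell here as well. Of 14 genes of mature granule neurons 10 fell, 12 when adjusted over the list alone, and Gabra6 went from 354 ± 123 to 80.8 ± 93.7 FPKM (log2 fold -3.21 ± 1.13, adjusted p = 0.0438). It stood at 261, 128 and 159 FPKM in hGFAP-Gnas 1, 2 and 7, and at 4.48 to 59.9 FPKM in the other 5. Of 13 Purkinje genes 12 fell, 13 when adjusted over the list alone. Calb1 went from 344 ± 113 to 76.3 ± 82.2 FPKM (log2 fold -3.19 ± 1.11) and Slc1a6, a glutamate transporter of Purkinje cells, had a log2 fold of -2.93 ± 0.76. Of 11 genes of inhibitory interneurons 8 fell, including Gad1 (-2.98 ± 0.92) and Slc32a1 (-2.94 ± 0.92). Of 19 cAMP signaling genes 9 fell, 10 when adjusted over the list alone, and 3 rose; Adcy1 had a log2 fold of -2.53 ± 0.83 and Gnal of -2.21 ± 0.58. Of 14 immediate early genes 6 fell, 8 when adjusted over the list alone, with Arc at -1.62 ± 0.43 and Bdnf at -1.50 ± 0.22. These 5 lists were called lower (camera adjusted p = 8.98e-06, 1.31e-06, 4.71e-05, 0.00587 and 1.12e-04), and with an estimated correlation each had an adjusted p of 0.392.

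Among glial and immune genes, 13 of 15 genes of microglia and macrophages rose, 14 when adjusted over the list alone. Cd68 went from 3.63 ± 0.467 to 56.4 ± 21.6 FPKM (log2 fold 3.42 ± 0.57) and Tyrobp, a signaling adaptor of myeloid cells, rose by 3.23 ± 0.56 (list camera adjusted p = 1.09e-05, and 0.392 with an estimated correlation). Of 11 oligodendrocyte precursor genes 7 rose, and Pdgfra went from 5.59 ± 0.535 to 86.7 ± 48.1 FPKM (log2 fold 3.42 ± 0.65; list camera adjusted p = 0.00650, and 0.424 with an estimated correlation). Of 13 genes of mature oligodendrocytes 2 fell, Opalin (-1.98 ± 0.42) and Ugt8a (-1.20 ± 0.32). That list was called lower (camera adjusted p = 1.21e-04, 0.392 with an estimated correlation, and 0.0629 with fry). Of 18 lists that camera called here fry passed 14, and the others it did not pass were cAMP signaling (0.0910), synapses (0.0903) and blood (0.0999). Of 14 genes of Bergmann glia and astrocytes, Gfap, an intermediate filament that reactive astrocytes raise, went from 54.5 ± 6.63 to 526 ± 287 FPKM (log2 fold 3.05 ± 0.46), 3 fell and 10 were not called. Adjusted over the list alone 1 rose and 1 fell, and the list was not called (camera adjusted p = 0.0614). Lcn2, a lipocalin secreted in inflammation, had the largest rise of the genes that the naming rule covers, from 0.515 ± 0.330 to 161 ± 95.8 FPKM (log2 fold 6.46 ± 0.60). None of 12 vascular genes was called, and limma gave Ttr an adjusted p of 0.811.

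In total 5570 of 14305 tested genes were called, 3738 higher and 1832 lower, and 3116 of them changed at least 2-fold. The share of higher genes was 67.1%, and it was 49.8% after quantile normalization and 55.0% after upper quartile scaling, which moved the median log2 fold of all genes from 0.19 to -0.01 and 0.04. The count was 1049 without Ctrl 1, 818 without Ctrl 2 and 1924 without Ctrl 3, each of which ended 16 to 19 of the 40 calls among the genes followed here, those of Gabra6, Calb1 and Gad1 included, and 8164 without hGFAP-Gnas 1, the library nearest to Ctrl, in which Mki67 stood at 2.70 FPKM and Atoh1 at 0.937 FPKM. Within depth classes, 6 genes were called among the deeper libraries and none of the 40 kept its call (Gli1 2.38, adjusted p = 0.259). The deeper libraries include hGFAP-Gnas 1, so depth was not told apart from the effect of this library there. Among the shallower libraries, Ddx3y stood at 0.0228 FPKM in Ctrl 3 and at 13.1 to 16.5 FPKM in hGFAP-Gnas 5 to 8. Y-linked signal was thus not told apart from the knockout in that class. In all, 2277 were called among the shallower ones with their 1 Ctrl library, where 16 of the 40 lost their calls, 5257 with the class as a term, which ended the calls of Gabra6, Calb1, Cbln3, Aldoc and Cdon, and 5726 with Y-linked signal as a term. Leaving out hGFAP-Gnas 8 or the filter ended the calls of those 5, leaving out hGFAP-Gnas 3, 4, 5 or 6 that of Adcy1 as well, and leaving out hGFAP-Gnas 2 or an offset of 0.1 that of Cdon alone. The replicate block ended all 40, and an adjusted p under 0.01 left 921 genes.

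**Figure D2:**
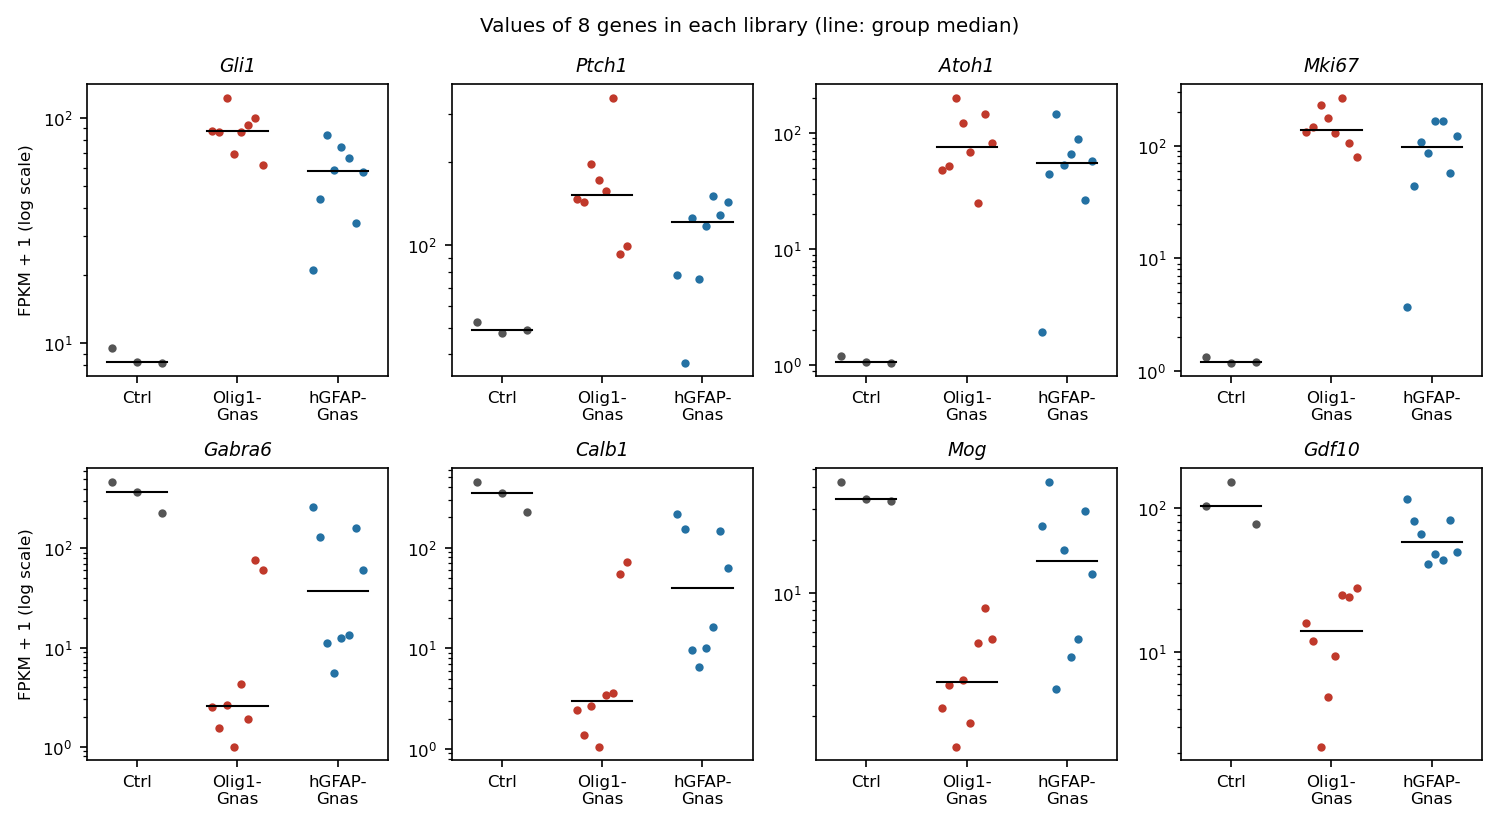
FPKM + 1 of 8 genes in each library on a log axis, each point a library and each line a group median. Gli1, Atoh1 and Mki67 were higher and Gabra6, Calb1 and Mog lower in both knockouts by median. hGFAP-Gnas 1 lay lowest of its group for Gli1 (20.1 FPKM), and Gdf10 separated the knockouts, at 14.2 ± 9.72 FPKM in Olig1-Gnas and 64.9 ± 26.1 FPKM in hGFAP-Gnas.

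Both knockouts shared most of their changes. Across 14015 genes tested in both, which are not independent of each other, the log2 folds had a Pearson correlation of 0.956 and a covariance of 1.41, and 92.4% had the same sign. Genes called in both numbered 3352 higher and 1743 lower, and none was called in opposite directions; independent lists of these sizes would share 1334 and 436. Of the genes called in hGFAP-Gnas, 92.5% were called the same way in Olig1-Gnas. Both comparisons use the same 3 Ctrl libraries. Unchanged groups were simulated with 3 shared Ctrl values, drawn anew for each gene from its Ctrl mean and SD. They gave a correlation of 0.546, a covariance of 0.0661, 61.1% of the same sign and a mean overlap of 0.2 genes. Noise was drawn for each gene on its own, so these runs do not show what shared Ctrl libraries give when genes move together. The covariances differed by 1.35. Since 3 Ctrl libraries cannot be split into parts of at least 2, part of the excess of shared calls over independent lists may come from sharing them. Folds were smaller in hGFAP-Gnas for 4588 of the 5095 genes called in both, with a median ratio of 0.758; without hGFAP-Gnas 1 these were 4166 and 0.844. Among those with the largest mean fold, Igfbpl1, Insm1, Nhlh1, Top2a and Mki67 had lower and Gabra6, Calb1, Cbln3, Slc17a7 and Rgs8 higher means in hGFAP-Gnas than in Olig1-Gnas. None of these 10 passed the test between the knockouts (for Mki67, log2 fold -1.19 ± 0.62, adjusted p = 0.241; for Gabra6 2.88 ± 1.08, 0.168). With folds of this size, that does not show equal levels. Without hGFAP-Gnas 1 the fold of Igfbpl1 turned from -0.40 to 0.18, and that of Mki67 was -0.61.

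**Figure D3:**
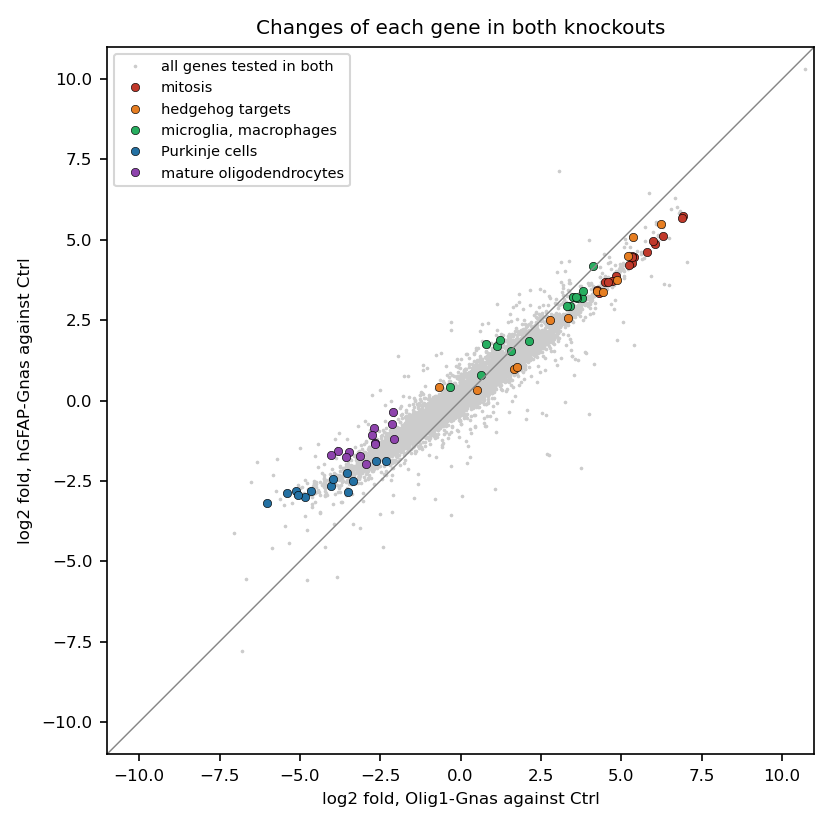
The log2 fold of each gene tested in both comparisons, Olig1-Gnas against Ctrl on the x axis and hGFAP-Gnas against Ctrl on the y axis; gray points are all 14015 genes, colored points members of 5 fixed lists, and the line marks equal folds. Genes of mature oligodendrocytes and Purkinje cells lie above the line on the negative side, with means of -2.93 and -4.19 in Olig1-Gnas against -1.32 and -2.62 in hGFAP-Gnas.

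Compared directly, hGFAP-Gnas and Olig1-Gnas differed in 59 of 14386 tested genes, 38 higher and 21 lower in hGFAP-Gnas. The clearest was Prm1, a protamine of sperm chromatin on chromosome 16 at 10796424 to 10796916 of mm9. It stood at 0.220 ± 0.316 FPKM in Olig1-Gnas and 107 ± 47.5 FPKM in hGFAP-Gnas (log2 fold 6.38 ± 0.25, adjusted p = 9.71e-11), and at 0.380, 0.964 and 73.2 FPKM in Ctrl 1, 2 and 3. Also higher in hGFAP-Gnas were Dmrtb1 (2.63 ± 0.49), the epidermal keratin gene Krt10 (2.52 ± 0.49), the Bergmann glia factor Gdf10 (2.42 ± 0.46) and the neutrophil-attracting chemokine gene Cxcl5 (1.88 ± 0.39). Lower were Gdpd3 (127 ± 25.3 FPKM in Olig1-Gnas and 12.2 ± 21.6 FPKM in hGFAP-Gnas, log2 fold -4.46 ± 0.58), the homeobox gene Dlx6 (-3.46 ± 0.39), Gpat2 (-2.79 ± 0.32) and the neighboring X-linked genes Xlr3b (-2.42 ± 0.44) and Xlr3c (-2.39 ± 0.37), near-identical copies whose values are uncertain. In the Ctrl libraries, Dlx6 was listed at 0 FPKM, Gpat2 stood at 0.292 to 0.462 FPKM and Gdpd3 at 9.48 to 27.1 FPKM. Gdpd3 stood at 62.6 FPKM in hGFAP-Gnas 3, 22.3 FPKM in hGFAP-Gnas 1 and at most 2.71 FPKM in the rest of that group. By list, all 13 genes of mature oligodendrocytes were higher in hGFAP-Gnas when adjusted over the list alone, and 1 of them over all genes, with a mean log2 fold of 1.61. Adjusted over the list alone, 7 of 14 genes of mature granule neurons, 5 of 13 Purkinje genes and 7 of 14 genes of Bergmann glia and astrocytes were higher too, against 0, 0 and 1 over all genes, and of 12 hedgehog targets 2 were lower and 1 higher. Camera called the oligodendrocyte, granule neuron, Purkinje and Bergmann glia lists higher (adjusted p = 3.98e-09, 4.41e-05, 4.41e-05 and 6.65e-05) and the mitosis list lower (1.50e-05), and with an estimated correlation each had an adjusted p of 0.616. The test fry, which asks whether the genes of a list move one way, passed 3 of the 13 lists that camera called; its adjusted p for these 5 was 0.0354, 0.150, 0.150, 0.0742 and 0.204. The mean log2 fold of mitosis genes was -1.005, and -0.52 without hGFAP-Gnas 1. Microglia genes were not called (camera adjusted p = 0.827, mean log2 fold 0.01; without hGFAP-Gnas 1, 0.180 and 0.31). The count was 3 with Y-linked signal as a term (Prm1, Dlx6 and Gpat2), 3 among the deeper and 51 among the shallower libraries, and 166 with the depth class as a term. Of the 59 genes, 1 was called among the deeper libraries, which include hGFAP-Gnas 1, 18 among the shallower ones and all 59 with the class as a term. Among the shallower libraries every hGFAP-Gnas and no Olig1-Gnas library held Y-linked signal, so knockout and Y-linked signal were not told apart there. The count was 24 among genes of at least 5 FPKM, 25 with the replicate number as a block, and 10 at an adjusted p under 0.01. It was 11 without hGFAP-Gnas 8, 104 without hGFAP-Gnas 3, and between 23 and 35 without Olig1-Gnas 2, 4 or 5 or hGFAP-Gnas 2, 4 or 7, several of which ended the calls of Cxcl5, Dmrtb1, Gdf10, Krt10 and Xlr3b; the share of higher genes, 64.4%, was 48.2% after quantile normalization.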

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

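The search for single distant libraries was planned before the data were examined, while the genes it was run on were those the report names. Chosen after seeing the results were the tests of a swap, of the mitosis score of hGFAP-Gnas 1, of Prm1, and of chromosome 6 except its count of stretches. Of 182 groups searched, 34 held a distant library, against 9.1 that chance gives at 1 in 20, and 28 of the 34 were hGFAP-Gnas 1. The searches share libraries and genes and are not independent. A single unusual library is counted many times, so the excess over 9.1 was not tested.

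In hGFAP-Gnas 1, the following genes of dividing cells and progenitors were lowest of the group. Values there were 2.70 FPKM for Mki67, 2.69 FPKM for Top2a, 1.86 FPKM for Birc5 and 4.85 FPKM for Mcm6. They were 0.937 FPKM for Atoh1, 5.16 FPKM for Igfbpl1, 7.91 FPKM for Insm1 and 3.40 FPKM for Nhlh1. Mycn (3.54 FPKM), Ccnd1 (9.09 FPKM), Sfrp1 (8.75 FPKM) and Smo (8.71 FPKM) were lowest as well, while Ptch1 (76.6 FPKM), Cntn2 (65.2 FPKM) and Zic5 (9.79 FPKM) were not. Also lowest were Cdkn2c (3.88 FPKM), Eda2r (1.10 FPKM) and Krt10 (2.06 FPKM), and the myeloid genes Cd68 (7.13 FPKM), C1qb (38.9 FPKM) and Tyrobp (19.7 FPKM). Bdnf, at 1.67 FPKM, was highest there. As mean log2 differences from Ctrl, its scores were 1.00 for mitosis, 0.37 for DNA replication, 0.53 for hedgehog targets, 0.65 for granule progenitors, 0.33 for microglia and macrophages, 0.0641 for T lymphocytes and 0.15 for chromatin regulators, each the lowest. Scores of blood (0.67) and cAMP signaling (-0.20) were the highest. Other distant values were Nkx2-2 in hGFAP-Gnas 3 (14.1 FPKM, the others at most 6.48 FPKM), Gpat2 and Mycn in Olig1-Gnas 6 (1.30 and 50.3 FPKM), the granule progenitor score there (3.23), Ugt8a in Olig1-Gnas 3 (0.737 FPKM) and the choroid plexus score in Olig1-Gnas 8 (2.01).

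The first pattern weighed is the nearness of hGFAP-Gnas 1 to Ctrl, whose median correlation across genes was 0.926 with Ctrl and 0.776 with its own group. A swap with a Ctrl library is not in line with the data, since 0 Ctrl libraries lay closer to hGFAP-Gnas than to Ctrl. The planned test of a wrong label on an animal like Ctrl gave what such a label predicts. Of the 281 genes high in this library alone, 40.2% were 2-fold higher in hGFAP-Gnas 2 to 8, no more than the highest Ctrl share (39.1 to 45.5%). The Ctrl shares rest on 15, 11 and 92 genes. A mitosis score of 1.00, against at most 0.06 in Ctrl, argues against such a label, though it was chosen after the values were seen. Scores of granule progenitors (0.65, Ctrl at most 0.07), hedgehog targets (0.53, at most 0.09) and DNA replication (0.37, at most 0.03) lay above Ctrl too. Those of interferon genes (-0.12) and hedgehog components (0.01) lay within the Ctrl range. If a small share of tissue like that of the other knockouts were mixed into tissue like Ctrl, all lists would reach 1 percentage of their rise. Mitosis genes reached a median of 2.33% (interquartile range 2.09 to 3.34), microglia genes 5.88% (3.56 to 8.59) and neural stem genes 16.3%. The ranges of some other lists overlapped that of mitosis, among them granule progenitors (3.06%, 1.53 to 4.53), hedgehog targets (3.28%, 1.98 to 9.63) and DNA replication (1.76%, 0.66 to 3.30). These percentages start from the Ctrl mean and leave out the spread between Ctrl animals. The microglia and macrophage score ran from -0.15 to 0.27 in Ctrl, against 0.33 in hGFAP-Gnas 1. Unequal percentages of this size therefore cannot decide whether such a mixture is present. An early or small growth with its own proportions remains a candidate that these data cannot test.

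The second pattern is a shift of chromosome 6 in Olig1-Gnas, with a median log2 fold 0.243 ± 0.118 above the other autosomes (n = 8, exact permutation p = 0.0242, adjusted p = 0.0768) and 0.0895 ± 0.0971 in hGFAP-Gnas. A few genes or a local cluster could not give it, since 9 of 10 stretches along the chromosome lay above the other autosomes. The shift was present in both depth classes, at 0.212 to 0.306 in the deeper Olig1-Gnas libraries and 0.307, 0.333 and 0.338 in the shallower Olig1-Gnas 1, 2 and 3. The ranges overlap only through the shallower Olig1-Gnas 4, at -0.0242. Whether depth adds to the size of the shift therefore stays open. A growth state common to both knockouts is hard to reconcile with 4 of 15 libraries that held Mki67 at over 100 times Ctrl and a shift under 0.1, but 3 of them are hGFAP-Gnas 5, 7 and 8 and only Olig1-Gnas 4 is of the group, so a state peculiar to Olig1-Gnas stays open. The shift is not peculiar to chromosome 6: chromosomes 2, 12, 14 and 15 had smaller ones in Olig1-Gnas that passed (-0.0937, -0.132, 0.0849 and -0.111, permutation adjusted p = 0.0288 each), and chromosomes 2 and 15 also differed between the knockouts (permutation adjusted p = 0.00591 each), so what moves these chromosomes stays open, and DNA was not analysed here.

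The third pattern is Prm1, at 48.4 to 199 FPKM in hGFAP-Gnas, at most 0.720 FPKM in Olig1-Gnas and at 73.2 FPKM in Ctrl 3. Testis RNA is not in line with Prm2, Tnp1 and Tnp2, which reached at most 0.365% of Prm1. RNA carried over from hGFAP-Gnas into Ctrl 3 would be 68.6% of that library and bring Mki67 to 63.7 FPKM, and it stood at 0.215 FPKM; depth is no candidate, as 0 shallower Olig1-Gnas libraries held Prm1 above 10 FPKM. A Cre transgene that carries a piece of Prm1, as some constructs do, could explain the values if Ctrl 3 at 73.2 FPKM carried Cre as well, and the labels used here do not tell. Alleles and transgene sequence were not analysed here.

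Between the knockouts, named genes with a difference were, as log2 folds of hGFAP-Gnas over Olig1-Gnas, Prm1 (6.38), Dmrtb1 (2.63), Krt10 (2.52), Gdf10 (2.42), Cxcl5 (1.88), Xlr3c (-2.39), Xlr3b (-2.42), Gpat2 (-2.79), Dlx6 (-3.46) and Gdpd3 (-4.46). Lists called by camera with its preset correlation had mean log2 folds of 1.61 for mature oligodendrocytes, 1.57 for Purkinje cells, 1.56 for mature granule neurons, 0.95 for inhibitory interneurons, 0.93 for Bergmann glia and astrocytes, 0.86 for synapses and 0.31 for cAMP signaling. They were -0.38 for chromatin regulators, -0.52 for hedgehog targets, -0.60 for cell cycle inhibitors and p53 targets, -0.70 for blood, -0.74 for DNA replication and -1.005 for mitosis. Without hGFAP-Gnas 1, all 13 kept their direction and their call, oligodendrocyte precursors were called as well (0.50 before, camera adjusted p = 0.0700; 0.72 after, 0.00464), and those of chromatin regulators, hedgehog targets, DNA replication and mitosis shrank by over 1.5 times, to -0.19, -0.21, -0.36 and -0.52. Several of them differed between the depth classes. From deeper to shallower libraries, mature granule neurons went from 0.91 to 2.21, Purkinje cells from 0.78 to 2.48 and Bergmann glia and astrocytes from 0.49 to 1.37. Inhibitory interneurons went from 0.78 to 1.28 and synapses from 0.56 to 1.25. Mitosis went from -1.45 to -0.55, DNA replication from -1.02 to -0.46, hedgehog targets from -0.82 to -0.22 and chromatin regulators from -0.51 to -0.25. Purkinje and synapse lists lost their calls in the deeper libraries (camera adjusted p = 0.0505 each), and hedgehog target, chromatin regulator and blood lists in the shallower ones (0.174, 0.174 and 0.384), where the fold of blood stayed (-0.69 and -0.73). Called in the deeper libraries alone were granule progenitors (-0.80, camera adjusted p = 0.00559), interferon genes (0.83, 0.0105) and choroid plexus (-1.09, 0.0496). The deeper libraries include hGFAP-Gnas 1, lowest of its group for mitosis, DNA replication, hedgehog targets, chromatin regulators and granule progenitors. For these lists, depth class and this library were not told apart. Among the shallower libraries, Ddx3y was listed at 0 FPKM in Olig1-Gnas 1 to 4 and at 13.1 to 16.5 FPKM in hGFAP-Gnas 5 to 8. Differences between the knockouts in that class were therefore not told apart from Y-linked signal, for any list. Over all libraries, granule progenitors differed by -0.44, and by -0.06 without hGFAP-Gnas 1. With Y-linked signal as a term, mature granule neurons (0.63, camera adjusted p = 0.0811), inhibitory interneurons (0.53, 0.0610) and synapses (0.33, 0.307) lost their calls. The other 10 kept theirs, mitosis at -0.72 and mature oligodendrocytes at 1.27, and 4 of these shrank by over 1.5 times: Purkinje cells to 0.77, Bergmann glia and astrocytes to 0.55, hedgehog targets to -0.30 and cAMP signaling to 0.18. That term added calls of granule progenitors (-0.43, camera adjusted p = 0.0146), oligodendrocyte precursors (0.64, 0.00466), choroid plexus (-0.84, 0.00371), meninges (0.49, 0.0292) and interferon genes (0.69, 0.00697). None of the 13 lists passed with an estimated correlation, and 3 passed fry.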

How the results depend on the processing

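For Olig1-Gnas, a 2-fold minimum left 4955 genes (2819 higher, 2136 lower), the shallower libraries called 5141 (1633 lower), leaving out libraries gave 6971 to 9546, and zeros taken as missing made Gnas -3.63; Kl alone changed direction, -2.35 in the shallower libraries. For hGFAP-Gnas, a 2-fold minimum left 3116 (2062 higher, 1054 lower), an adjusted p under 0.01 left 921 (757, 164), the deeper libraries 6 (6, 0), the shallower ones 2277 (1949, 328) and the replicate block 0 (0, 0; limma gave 7353 genes an unadjusted p under 0.05 in the main test). Leaving out libraries gave 818 to 8164 (681 to 5404 higher, 137 to 2760 lower), fewest without Ctrl 2 and most without hGFAP-Gnas 1; the cause was not tested. Between knockouts, against 59 genes, the offset of 0.1 gave 23 higher, the 5 FPKM filter 24 (11 higher, 13 lower), the block 25 (15, 10), the 2-fold minimum 39 (22 higher), an adjusted p under 0.01 10 (1, 9), the deeper libraries 3 (2, 1), the depth class as a term 166 (123, 43) and the Y-linked term 3 (1, 2). Leaving out libraries gave 11 to 104 (2 to 63 higher, 9 to 41 lower). Camera called 17, 18 and 13 lists at the preset correlation, and with an estimated correlation 0, 0 and 0. Replicate numbers did not pair libraries: residual correlations between the groups ran from -0.17 to 0.25, highest for the own number in 0 of 3, 1 of 3 and 0 of 8, so the block ties unrelated libraries and drops the knockouts whose number no Ctrl has. Other settings kept the counts within 1.5 times. Alternatives planned for tables holding only the authors' comparison were not run, as the tables hold values per library. Depth limits low genes: the shallower libraries hold 0.268 to 0.429 of the fragments of Ctrl 2.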

Other observations

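Markers of medulloblastoma subgroups, lists of few genes, moved unevenly. Of 5 markers of the hedgehog subgroup 3 rose and 1 fell in Olig1-Gnas and 3 rose in hGFAP-Gnas (camera adjusted p = 0.217 and 0.177). Of 6 group 3 markers, only 2 passed the filter in Olig1-Gnas, and these 2 rose (camera adjusted p = 0.0379, and 0.242 with an estimated correlation). In hGFAP-Gnas 4 passed it and 2 rose (camera adjusted p = 0.156). Of 5 group 4 markers 4 fell and 1 rose in Olig1-Gnas, and 3 fell in hGFAP-Gnas (camera adjusted p = 0.0354 and 0.0193, and 0.284 and 0.392 with an estimated correlation). Of 6 WNT subgroup markers 1 rose and 1 fell in each knockout (0.879 and 0.959). Of 12 chromatin regulators 9 rose in Olig1-Gnas, among them Uhrf1 (6.02 ± 0.20), which maintains DNA methylation, and Ezh2 (3.79 ± 0.55), the polycomb methyltransferase, and 8 rose in hGFAP-Gnas (camera adjusted p = 0.00106 and 0.00447, and 0.242 and 0.424 with an estimated correlation). Of 14 synaptic genes 10 fell and 1 rose in Olig1-Gnas, Snap25 having a log2 fold of -3.58 ± 0.67, and 8 fell and 1 rose in hGFAP-Gnas (camera adjusted p = 6.00e-04 and 9.11e-04, and 0.300 and 0.392 with an estimated correlation).

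Interferon genes rose in part: 3 of 10 in Olig1-Gnas, 2 when adjusted over the list alone, and 5 in hGFAP-Gnas, 7 when adjusted over the list alone, with Bst2 at 2.83 ± 0.57 and 2.63 ± 0.69 on the log2 scale (camera adjusted p = 0.275 and 0.0193, and 0.531 in hGFAP-Gnas with an estimated correlation). In Olig1-Gnas the interferon score, as a mean log2 difference from Ctrl, was 2.69 and 2.77 in libraries 1 and 2, and 0.24 and -0.05 in 5 and 6. Libraries 1 and 2 were also the highest of Olig1-Gnas for microglia and macrophages (3.53 and 3.47, the others at most 2.33) and for T lymphocytes (1.68 and 2.17, the others at most 0.67). Neural stem cell genes rose in 6 of 12 and in 5 of 12 with 1 falling, Nes by 3.44 ± 0.26 and 2.84 ± 0.46, and were not called as a list (0.395 and 0.1). Hippo signaling genes were split, 4 of 14 rising and 3 falling in Olig1-Gnas and 4 rising and 2 falling in hGFAP-Gnas; Tead2 rose by 4.77 ± 0.26 and 3.59 ± 0.80 (camera adjusted p = 0.799 and 0.959). Vascular, choroid plexus and meningeal lists were not called in either knockout (camera adjusted p = 0.642, 0.686 and 0.432 in Olig1-Gnas, 0.463, 0.377 and 0.402 in hGFAP-Gnas). The blood list, of 4 genes with none called, was called lower in hGFAP-Gnas (camera adjusted p = 0.0337, and 0.424 with an estimated correlation; limma gave Hba-a1 an adjusted p of 0.0793). Of the T lymphocyte list only Cd4 was tested, with log2 folds of 2.15 ± 0.27 and 2.10 ± 0.46.

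Groups were shuffled to see how many calls other splits of the same libraries give. Of 100 splits of the Olig1-Gnas and Ctrl libraries, 1 called as many genes as the real one, that one itself, and the next called 5. For hGFAP-Gnas it was again 1, and the next split, Ctrl 2 exchanged with hGFAP-Gnas 1, called 4908. Between knockouts 2 splits reached the real count, and the larger one called 2245 genes against 59; it set Olig1-Gnas 1 to 6 with hGFAP-Gnas 5 and 6 against the others. A split that calls several times the real count points to a structure among these libraries other than the knockout, and what it follows was not tested. By lists, 11, 11 and 19 splits called as many as the real ones, with 19, 20 and 16 lists at most in another split. List counts thus did not stand out from those of other splits. Splits with Ctrl can keep part of the real contrast, as the one that called 4908 genes does. Such splits are not free of the knockout effect, so the list counts that chance alone gives were not shown. The preset correlation may be too low for lists of genes that move with cell composition.

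Whole-tissue RNA does not separate a change within cells from a change of cell proportions. List scores in Olig1-Gnas, as mean log2 differences from Ctrl, moved apart: -4.19 ± 1.22 for Purkinje cells, -3.71 ± 1.27 for mature granule neurons, -1.19 ± 0.82 for Bergmann glia and astrocytes, 0.02 ± 0.37 for vascular cells and 2.42 ± 0.68 for microglia and macrophages. Dilution of all resident cells alike would not give such values on its own. Fewer neurons and less expression in each neuron were not told apart here, and single-cell data would be needed.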
